A study of Mus musculus with 10 samples.

How the data were processed

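Expression was measured in 10 mice, 5 wild type and 5 Nkx2.2-/-, of the C57BL/6 strain. Per the labels' protocols the mice were perfused at 1.5 to 2 days after birth, the frozen brains were cut sagittally at 20 µm, and RNA extracted with TRIzol was turned into biotinylated cRNA by the array maker's standard method. The values deposited by the authors are log2 expression values, 1 per probe set and array, made with RMA per the submitters' processing notes; RMA corrects background, quantile-normalizes and summarises the probes of a probe set, and its version is not given in the sources used here. RMA draws the arrays to 1 distribution, so a change shared by most genes would not be seen, and it gives no detection call, so a difference between dim probe sets is compressed towards 0. The groups come from the sample titles. The number of arrays limits the precision. Litter and batch of each mouse were not used here, and sex entered only as a covariate read from expression in 1 alternative. Mice of 1 litter thus count as separate replicates, and the p-values of single genes measure the spread between mice.

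Of 45101 probe sets, 64 controls were left out. By the platform's annotation, 34945 of the other 45037 had 1 gene symbol, 932 had several and 9160 were unnamed here. The tests over genes used the first kind, with the probe set of highest mean over all 10 arrays standing for a gene, which gave 18193 genes. Of these 9010 had several probe sets. The RefSeq gene table of assembly GRCm38.p6 was matched by Entrez number for 18032 genes, changed 0 symbols, and served only for names and for which genes neighbour Nkx2-2. The build behind the array's probes is not given in the sources used here, so no coordinates are printed. No filter on dim probe sets was applied.

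Nkx2.2-/- and wild-type mice were compared with lmFit and eBayes of limma 3.58.1 under R 4.3.3, without covariates, with Benjamini-Hochberg adjustment over genes at 0.05. Log2 changes are Nkx2.2-/- minus wild type. An exact two-sided permutation test of 5 against 5 was added for Nkx2-2 and for the list scores, which are means of log2 values over the members of a list. The 36 gene lists covered myelin, newly formed oligodendrocytes, oligodendrocyte precursors, serotonergic, catecholaminergic and other neurons, other glia, vessels, meninges, blood, neighbouring tissues, regional Hox genes, proliferation, metabolism, stress responses and neighbours of Nkx2-2. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, beside camera with an estimated correlation and fry. With the preset correlation camera sets a list against other genes and takes the correlation of its members as fixed. Those p-values therefore do not measure the spread of a list between mice. Intervals of list means are 95% intervals from the scores of the mice. Preparation and figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

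The genes to be named were set by a rule: Nkx2-2, up to 12 genes each way with the largest change among those past the threshold with separated groups, the 5 of lowest p in a direction with fewer than 5 such genes, up to 4 members of each list past its threshold, and 18 genes always. This took in 66 genes, of which examples are given, and 2 of the 18 were not analysed here. The lists, this rule, the tests and most alternatives were chosen before the data were examined. The alternatives were quantile normalization, a common median, leaving out the dimmer genes, the mean of a gene's probe sets, a trend or robust prior, array weights, covariates for sex, red cell genes and caudal Hox genes, every probe set on its own, other thresholds, the other list tests, and leaving out each array. The sex covariate, Xist minus the mean of 3 Y-linked genes, used 1 gene fewer than planned. Chosen after seeing the data were leaving out the 2 arrays of low 5 prime Gapdh signal, their Gapdh difference as a covariate, the mean of the cerebellum list as a covariate, and lists without genes shared with the myelin or serotonergic list.

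The test was checked on 20 simulated sets of this comparison with 18193 genes, 200 of them changed. It recovered 76.5% of changes of 0.5 on the log2 scale, 96.5% of changes of 1, 99% of 1.5 and 99.6% of 2, and 6.11% of the called genes were false. The genes were simulated as independent. With 200 changed genes the Benjamini-Hochberg threshold is also easier to reach than in the real comparison, which called 11. These shares therefore do not give the recovery in the real data. Camera found the shifted list in 100% of sets and called 0% of unchanged lists, in data simulated without correlation between genes.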

Results

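The hindbrain and upper spinal cord of newborn mice without the transcription factor Nkx2.2, which acts in ventral neural progenitors and in cells of the oligodendrocyte lineage, were compared with those of wild-type littermates on expression arrays. RNA came from the pons, the medulla and the rostral spinal cord of mice aged 1.5 to 2 days, taken from 20 µm sections, with 1 array for each of 5 wild-type mice (replicates 14, 15, 16, 18 and 21) and 5 Nkx2.2-/- mice (replicates 11, 12, 22, 29 and 43). The question was which transcripts differ in the absence of Nkx2.2. Each array gave log2 RMA values for 45101 probe sets, between 3.52 and 13.2, with array medians from 5.07 to 5.12. Correlations between arrays, taken across the 18193 genes with 1 probe set each, ran from 0.972 to 0.996. On 2 arrays, 1 of each genotype, the 5 prime control probe set of Gapdh was dim against the 3 prime one. The difference was 2.13 in wild-type replicate 14 and 3.78 in Nkx2.2-/- replicate 43, against -0.32 to 0.13 on the other 8.

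The Nkx2-2 transcript, read by 1 probe set, separated the genotypes. It lay at 6.88, 6.47, 6.49, 6.51 and 6.42 in wild-type replicates 14, 15, 16, 18 and 21, and at 4.73, 4.34, 4.24, 4.58 and 4.64 in Nkx2.2-/- replicates 11, 12, 22, 29 and 43. The means were 6.55 ± 0.186 and 4.51 ± 0.207 (SD, n = 5 each), a log2 change of -2.05 with a 95% interval of -2.29 to -1.80, or 4.13-fold lower (limma, Benjamini-Hochberg adjusted p = 3.5e-05). The exact two-sided permutation test gave p = 0.00794, the smallest that 5 against 5 can give. The wild-type mean lay above 79.7% of probe sets and the Nkx2.2-/- mean above 22.3%. Where the probe set lies relative to the targeted part of the gene was not known here, so it checks the labels only as a signal that separates the groups.

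As lists, myelin genes and genes of serotonergic neurons were lower in the Nkx2.2-/- mice, in 30 of 36 and 10 of 14 members by sign. Genes of oligodendrocyte precursors did not pass as a group. Besides Nkx2-2 itself, 10 genes fell: Mbp, Cnp, Mobp, Mag, Cldn11 and Ugt8a of the myelin list, Tph2 and Slc6a4 of the serotonergic list, and Plxnb3 and Gchfr, which are in no list. By the probe set standing for each gene, the largest change was in Mbp, myelin basic protein, which was 6.67-fold lower. Tph2, the rate-limiting enzyme of serotonin synthesis in the brain, was 2.72-fold lower. Its Nkx2.2-/- mean lay above 15.5% of probe sets, so that fold may be compressed. No gene rose among the 18193 tested.

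Of 36 measured myelin genes, 6 fell by the test over all genes and 18 fell when adjusted over the list alone, and none rose by either (limma with Benjamini-Hochberg). Mbp went from 10.8 ± 0.245 in wild type to 8.05 ± 0.499 (SD, n = 5 each), a log2 change of -2.74 (SE 0.217, limma adjusted p = 7.9e-04). Cnp, which encodes an enzyme abundant in oligodendrocytes, changed by -0.97 (SE 0.096, limma adjusted p = 0.00303). Cldn11, the claudin of myelin tight junctions, changed by -1.14 (SE 0.134), and Mag, a glycoprotein of the inner myelin membrane, by -0.60 (SE 0.0701), both with a limma adjusted p of 0.00998. Mobp changed by -0.72 (SE 0.076, limma adjusted p = 0.00435) and Ugt8a, the transferase that makes galactosylceramide, by -1.07 (SE 0.154, limma adjusted p = 0.0451). Plxnb3, a plexin receptor, changed by -0.62 (SE 0.0616, limma adjusted p = 0.00303). Mog and Myrf, the latter a transcription factor of myelination, had log2 changes of -0.30 and -0.34 and did not pass over all genes (limma adjusted p = 0.233 and 0.617), though both passed within the list alone. The mean log2 change over the list was -0.34 with a 95% interval of -0.44 to -0.24, and the list score was lower in all 5 Nkx2.2-/- mice than in any wild-type mouse. Limma's camera gave the list an adjusted p of 3.4e-32 with a preset correlation, and adjusted p = 0.00797 with an estimated correlation. Without wild-type replicate 14 and Nkx2.2-/- replicate 43, the arrays of low 5 prime Gapdh signal, that second value was 0.0824 at a mean change of -0.34, and with their Gapdh difference as a covariate it was 0.0295, both settings chosen after seeing the data.

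Not all probe sets of a gene moved alike. Over every non-control probe set 23 fell and 0 rose (limma, Benjamini-Hochberg). For Mbp 5 of 8 probe sets passed, with log2 changes from -2.74 to 0.02, and for Mobp 3 of 5, from -1.59 to 0.05. For Cnp 1 of 3 passed, and for Ugt8a and Plxnb3 1 of 2 each. The other called genes had 1 probe set.

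**Figure D1:**
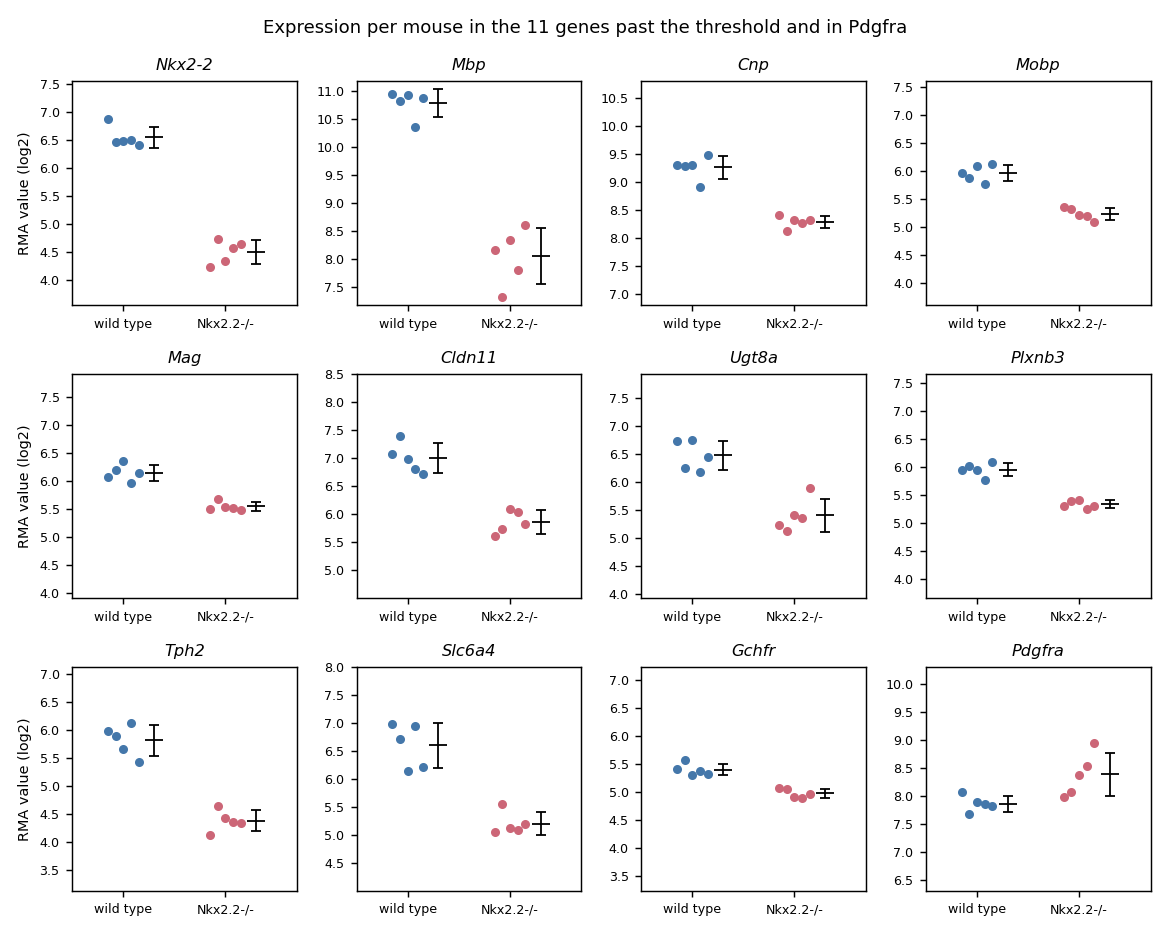
Log2 RMA value per mouse (points, 5 wild type and 5 Nkx2.2-/-) for the 11 genes past the threshold and for Pdgfra, with the mean and SD as bars; the vertical axes of all panels cover the same span. In each of the 11 genes every Nkx2.2-/- mouse lies below every wild-type mouse, whereas the groups overlap for Pdgfra.

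Of 14 measured genes of serotonergic neurons, 2 fell over all genes and 7 when adjusted over the list alone (limma with Benjamini-Hochberg). In sign, 10 were lower and 4 higher. All 4 higher members, named outside the rule, were Lmx1b, Htr1a, Tac1 and Gata2. Their log2 changes were 0.15, 0.11, 0.07 and 0.05, and none rose by either test. Tph2 went from 5.82 ± 0.278 to 4.38 ± 0.186 (SD, n = 5 each), a log2 change of -1.44 (SE 0.133, limma adjusted p = 0.00242). Slc6a4, the serotonin transporter, went from 6.60 ± 0.400 to 5.20 ± 0.202, a log2 change of -1.40 (SE 0.176, limma adjusted p = 0.0162). Ddc, the decarboxylase shared by serotonin and catecholamine synthesis, had a log2 change of -1.17 (limma adjusted p = 0.104), and Slc18a2, the vesicular monoamine transporter, one of -0.47 (limma adjusted p = 0.495). Gch1, the first enzyme of tetrahydrobiopterin synthesis, had a log2 change of -0.27 (limma adjusted p = 0.412). Gchfr, whose product regulates that enzyme, fell by 0.42 on the log2 scale (SE 0.059, limma adjusted p = 0.0378). The list's mean log2 change was -0.38 with a 95% interval of -0.48 to -0.28. Camera in limma gave an adjusted p of 4.0e-11 with the preset correlation, and adjusted p = 0.00797 with an estimated correlation.

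The 13 measured genes of noradrenergic and dopaminergic neurons had a mean log2 change of -0.18 (limma camera adjusted p = 0.00104, and adjusted p = 0.372 with an estimated correlation). None fell over all genes, and the 3 that fell when adjusted over the list alone, Ddc, Gch1 and Slc18a2, are also in the serotonergic list. Slc6a2, the noradrenaline transporter, had a log2 change of -0.36 (limma adjusted p = 0.9996) in its brightest probe set, and of 0.001, -0.004 and -0.04 in the others. Without the 3 shared genes the mean change was -0.05 (limma camera adjusted p = 0.694), in a run added after seeing the data.

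Genes of oligodendrocyte precursors did not pass as a group with all 10 arrays. Of 23 measured, 0 passed in either direction, over all genes or adjusted over the list alone (limma), and their mean log2 change was 0.01 with a 95% interval of -0.07 to 0.09 (limma camera adjusted p = 0.590). Nkx2.2-/- replicate 11 had the lowest score of all mice. Without it the mean was 0.04 and the other 4 Nkx2.2-/- mice lay above every wild-type mouse (exact two-sided p = 0.00794, unadjusted). Over the lists that p was 0.0476, or 0.0571 with Nkx2-2 left out of its list. Camera did not pass (limma adjusted p = 0.0740, and 0.228 with an estimated correlation). Leaving out the mouse of lowest score favours such a separation, so no rise is read from it. Olig1 and Olig2, transcription factors of the whole lineage, had log2 changes of 0.13 and 0.13, Sox10 of 0.06 and Cspg4 of 0.04. Pdgfra, the growth factor receptor of precursors, had the largest positive value of these, 0.52 (SE 0.161), with an unadjusted limma p of 0.00799 and an adjusted p of 0.9996. Its dimmer probe sets were at 0.115 and 0.058. Of 20 measured genes of committed precursors and newly formed oligodendrocytes, 0 fell over all genes and 6 fell when adjusted over the list alone (limma). The log2 changes of Enpp6, Itpr2 and Gpr17 were -0.27, -0.21 and -0.39, that of Tcf7l2 was -0.15 and that of Sirt2, also a myelin list member, was -0.48. These values are of the brightest probe sets. Dimmer ones were at -0.02 for Enpp6, from -0.18 to 0.06 for Itpr2 and from -0.09 to 0.001 for Tcf7l2. The mean change was -0.14 with a 95% interval of -0.26 to -0.02 (limma camera adjusted p = 5.0e-07, and adjusted p = 0.0840 with an estimated correlation). In 5 further runs with an estimated correlation, chosen after seeing the data, it passed in 2, with the Gapdh difference as a covariate (limma camera adjusted p = 0.0295) and without wild-type replicate 18 (0.0338). It did not pass in the other 3, without the arrays of low 5 prime Gapdh signal (limma camera adjusted p = 0.0824), with the cerebellum list as a covariate (0.0595) and without Nkx2.2-/- replicate 11 (0.122).

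The list of ventral interneuron and visceral motor neuron genes, which holds Nkx2-2 itself, had 10 measured members and a mean log2 change of -0.24 (limma camera adjusted p = 0.0627, and adjusted p = 0.250 with an estimated correlation). Only Nkx2-2 passed, over all genes and within the list alone, and the list's change came from it. In a run added after seeing the data, the 9 other members had a mean of -0.03 with a 95% interval of -0.10 to 0.03 and did not pass (limma camera adjusted p = 0.884, fry adjusted p = 0.958). Nor did they pass without any 1 array. Where the dimmer genes were left out, Nkx2-2 among them, the list's mean was 0.05. With Nkx2-2 in it, the list passed camera without wild-type replicate 18 (limma adjusted p = 0.0357) or Nkx2.2-/- replicate 11 (0.0224), 12 (0.0246) or 22 (0.0221), which restates the lower signal of that transcript. Sim1, a transcription factor of those interneurons, had a log2 change of 0.09. By limma's fry, which tests a list's own movement and does not set it against other genes, the myelin list (adjusted p = 7.6e-04) and the serotonergic list (adjusted p = 7.6e-04) passed, and this list (adjusted p = 7.6e-04) only with Nkx2-2 in it.

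Proliferation genes were lower in the Nkx2.2-/- mice in sign for 21 of 21 measured members, 0 of which fell over all genes and 8 when adjusted over the list alone (limma). Birc5, Ccnb2, Cdk1 and Top2a, genes of mitosis and chromosome segregation, had log2 changes of -0.56, -0.48, -0.62 and -0.61. The list's mean was -0.35 with a 95% interval of -0.65 to -0.05 (limma camera adjusted p = 3.0e-19, and adjusted p = 0.217 with an estimated correlation). Genes of cerebellar cells, from tissue next to the dissected regions, had a mean of -0.17 with an interval of -0.69 to 0.35 (limma camera adjusted p = 0.220). Wild-type replicate 18 was highest in its group for both lists, and so was Nkx2.2-/- replicate 11 in its own. The proliferation mean was -0.25 without the former (exact two-sided p = 0.0476) and -0.43 without the latter (exact two-sided p = 0.00794), against an exact p of 0.0397 with all arrays.

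Hox genes of the spinal cord were higher in sign in 15 of 15 measured members, with a mean of 0.26 and a 95% interval of -0.18 to 0.70 (limma camera adjusted p = 1.2e-05, and adjusted p = 0.250 with an estimated correlation). Hoxc8 had a log2 change of 1.33 (SE 0.454), Hoxb9 of 0.39, Hoxd8 of 0.32 and Hoxa7 of 0.21. None passed over all genes or within the list alone. The mean was 0.15 without wild-type replicate 18, 0.17 without Nkx2.2-/- replicate 29 and 0.39 without Nkx2.2-/- replicate 11, and replicates 18 and 11 had the lowest scores of their groups. Genes of cholesterol synthesis were lower in sign in 17 of 17, with a mean of -0.16 (limma camera adjusted p = 7.2e-05, and adjusted p = 0.597 with an estimated correlation). Fdps, Insig1, Hmgcs1 and Fdft1 had log2 changes of -0.27, -0.19, -0.27 and -0.18. Meningeal and fibroblast genes, with Lum at -0.33 and Col1a1 at -0.46, had a mean of -0.30 (limma camera adjusted p = 6.5e-05, and adjusted p = 0.601 with an estimated correlation). Genes of the unfolded protein response, with Manf at -0.30 and Calr at -0.27, had a mean of -0.12 (limma camera adjusted p = 4.3e-04, and adjusted p = 0.209 with an estimated correlation). Immediate early genes had a mean of -0.09 (limma camera adjusted p = 0.0284, and adjusted p = 0.689 with an estimated correlation), with Egr1 at -0.29 and Klf2 at -0.17. Microglial genes, with Ly86 at -0.20 and Csf1r at -0.11, had a mean of -0.07 (limma camera adjusted p = 0.0316, and adjusted p = 0.601 with an estimated correlation). Mural cell genes, with Rgs5 at -0.39 and Pdgfrb at -0.19, had a mean of -0.09 (limma camera adjusted p = 0.0376, and adjusted p = 0.601 with an estimated correlation). In these 7 lists 0 members passed over all genes and 0 when adjusted over the list alone.

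Single arrays moved several of these lists. The meningeal mean was -0.13 without wild-type replicate 15 and no longer passed (limma camera adjusted p = 0.102), and it was -0.47 without wild-type replicate 21. The cholesterol mean was -0.09 without Nkx2.2-/- replicate 11. The catecholaminergic list no longer passed without Nkx2.2-/- replicate 29 (mean -0.15, limma camera adjusted p = 0.227). Immediate early genes no longer passed without wild-type replicate 15 (mean -0.04, limma camera adjusted p = 0.628) or Nkx2.2-/- replicate 43 (-0.07, 0.381). Microglial genes no longer passed without wild-type replicate 15 (mean -0.06, limma camera adjusted p = 0.268), wild-type replicate 16 (-0.07, 0.113), Nkx2.2-/- replicate 11 (-0.04, 0.165) or Nkx2.2-/- replicate 43 (-0.05, 0.381). Mural cell genes no longer passed without any 1 of wild-type replicates 14, 15 and 16 and Nkx2.2-/- replicates 11, 29 and 43 (means from -0.11 to -0.05, limma camera adjusted p from 0.0628 to 0.357), and their mean was -0.14 without wild-type replicate 21.

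The other 22 lists, the cerebellar one among them, did not pass camera, and 0 of their members passed over all genes or within a list alone (limma). Among neuronal lists the mean log2 change was 0.02 for genes of most neurons (adjusted p = 0.435), 0.03 for motor and cholinergic neurons (adjusted p = 0.435), 0.03 for excitatory neurons (adjusted p = 0.590), -0.04 for inhibitory neurons (adjusted p = 0.600) and 0.04 for sensory ganglia (adjusted p = 0.805). Among glial and progenitor lists it was 0.0035 for astrocytes (adjusted p = 0.723), -0.06 for radial glia (adjusted p = 0.575), -0.03 for ventral patterning genes (adjusted p = 0.944), -0.04 for ependymal cells (adjusted p = 0.590) and -0.0039 for Schwann cells (adjusted p = 0.590). It was -0.28 for choroid plexus (adjusted p = 0.206), -0.01 for endothelium (adjusted p = 0.932), -0.02 for red cells (adjusted p = 0.935), and 0.01 for muscle and cartilage (adjusted p = 0.375). It was -0.12 for forebrain and midbrain genes (adjusted p = 0.405) and 0.03 for hindbrain Hox genes (adjusted p = 0.483). For responses to fasting it was -0.08 (adjusted p = 0.0976), to glucocorticoids -0.01 (adjusted p = 0.958), and to low oxygen or high osmolality -0.04 (adjusted p = 0.356). Ribosomal protein genes had a mean of -0.03 (adjusted p = 0.590), and neighbours of Nkx2-2 on its chromosome one of -0.05 (adjusted p = 0.590). Single arrays decided some of these results too. Without Nkx2.2-/- replicate 11 the preset correlation let pass the choroid plexus (mean -0.50, limma camera adjusted p = 2.0e-05), cerebellar (-0.31, 0.00142), forebrain and midbrain (-0.20, 0.00803), ependymal (-0.10, 0.00214) and radial glia lists (-0.09, 0.0499), lower. In the same run it let pass the motor and cholinergic (0.10, 0.00505), pan-neuronal (0.07, 0.0109) and hindbrain Hox lists (0.11, 0.0201), higher. With an estimated correlation none of these lists passed in that run (limma camera adjusted p from 0.122 to 0.446). The sensory ganglion and excitatory neuron means were 0.13 and 0.10 there (exact two-sided p = 0.0238 and 0.230, unadjusted). Without wild-type replicate 14 the choroid plexus (-0.43, limma camera adjusted p = 0.0115), cerebellar (-0.24, 0.0282) and ribosomal lists (-0.09, 0.00514) passed. Over all runs without 1 array the means reached up to -0.10 for choroid plexus, -0.02 for the cerebellum and -0.06 for forebrain and midbrain. The fasting list passed without wild-type replicate 21 (-0.11, limma camera adjusted p = 0.0233) or Nkx2.2-/- replicate 43 (-0.12, 0.0457). The Schwann cell list passed at 0.05 without wild-type replicate 15 (limma camera adjusted p = 0.0124), and the glucocorticoid list at 0.07 without wild-type replicate 21 (0.00388). In the precursor and sensory ganglion lists the median was below 0 while mean and test were above it, and in the Schwann cell list the test pointed up while mean and median lay below 0.

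**Figure D2:**
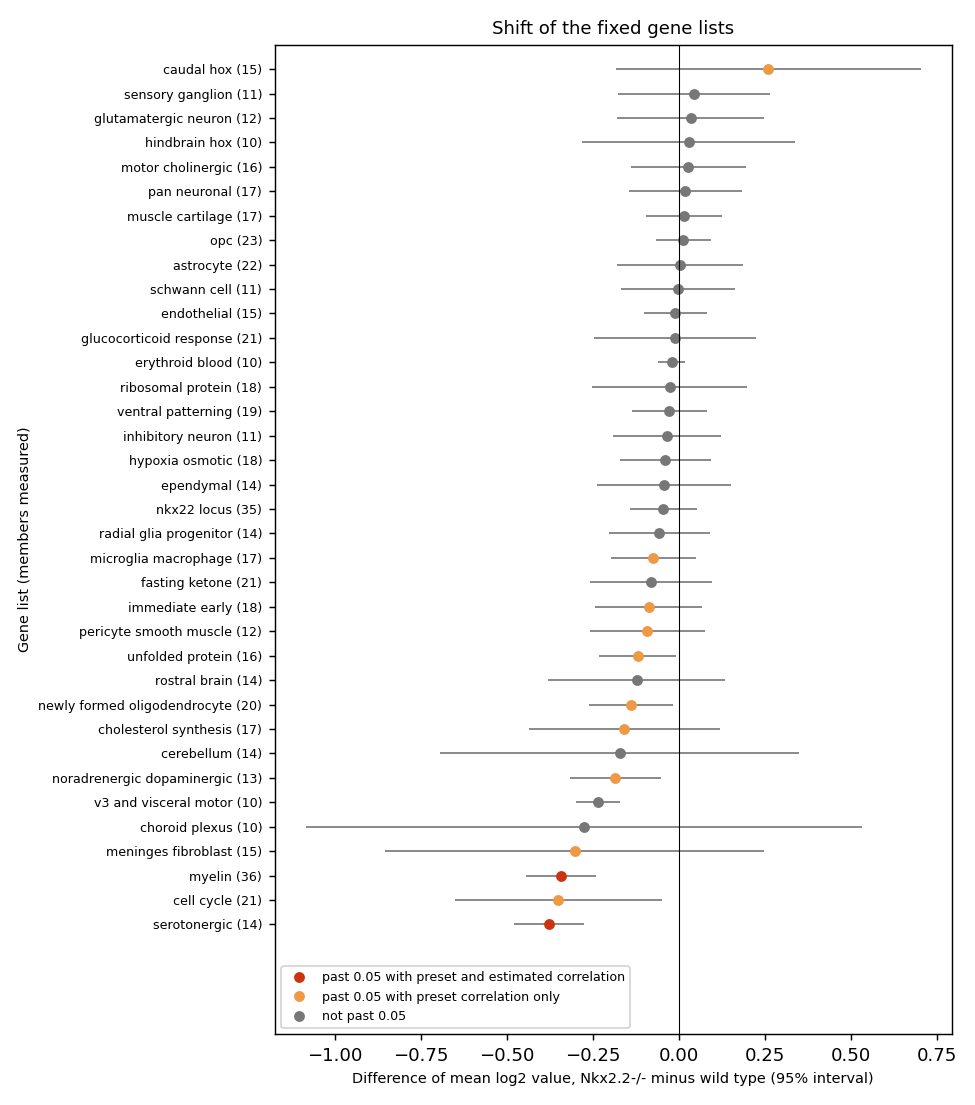
Difference between Nkx2.2-/- and wild-type mice in the mean log2 value of each of the 36 lists, with the number of measured members in brackets; points are differences of group means over 5 mice each and lines are 95% intervals. Colours give the camera result at 0.05; the myelin and serotonergic lists passed with both the preset and the estimated correlation.

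By the preset correlation 12 lists passed, 11 lower and 1 higher, against 2 with an estimated correlation, the myelin and serotonergic lists (limma camera). Exact two-sided permutation tests of the list scores gave 0 lists past the threshold after Benjamini-Hochberg adjustment. The lowest adjusted p was 0.0952, that of the 3 lists at the smallest possible p of 0.00794, the myelin and serotonergic lists and the list holding Nkx2-2. Adjusted over 36 lists, that smallest p passes only if several more lists also have p-values at or near it. The 0 therefore does not argue against a change of these 3 lists. Without Nkx2.2-/- replicate 11, 2 lists passed camera with an estimated correlation, the myelin and serotonergic lists (limma adjusted p = 0.0256 each). With the preset correlation 19 lists passed camera in that run and 6 passed on their scores, the list holding Nkx2-2 among them in both. With Nkx2-2 left out of that list, 16 passed camera and 0 on their scores. The myelin, serotonergic, catecholaminergic and proliferation lists, lower, and the precursor list, higher, were then at an adjusted p of 0.0571 by score, against 0.0476 before. Their scores were the same in both cases, and only the number of lists at the smallest possible p differed. The immediate early and radial glia lists no longer passed either (limma camera adjusted p = 0.0526 each).

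**Figure D3:**
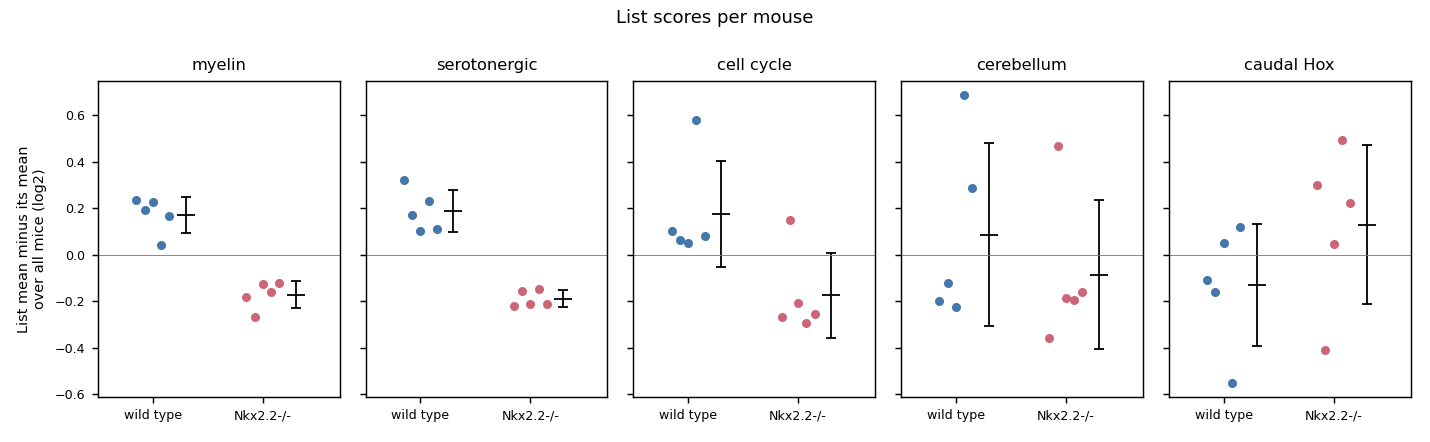
List scores per mouse (points) for 5 lists, as the mean log2 value of the members minus the list's mean over all 10 mice, with group means and SD as bars. For the myelin and serotonergic lists every Nkx2.2-/- mouse lies below every wild-type mouse, whereas the cell cycle, cerebellum and caudal Hox scores overlap.

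Across all 18193 genes 11 fell and 0 rose (limma, Benjamini-Hochberg). At an unadjusted p under 0.05 there were 587 genes, 493 lower and 94 higher, and the median log2 change over all genes was -0.0042. The 587 were 3.23% of all genes, a smaller share than that threshold gives by chance, so p-values under 0.05 as a whole were not in excess. That share does not bear on the 11 called genes, whose unadjusted limma p was 2.7e-05 or lower. The 5 genes of lowest p among those higher, none of which passed, were Fam89a, Sh3bgr, Spaca6, Per2 and Pax1, with log2 changes of 0.18, 0.27, 0.17, 0.15 and 0.16 and limma adjusted p from 0.641 to 0.9996. The groups did not overlap for 124 genes, 0.682% of those tested, against 0.794% by chance, and all 11 called genes were among them. Leaving out single arrays ended some calls. Without wild-type replicate 15, Nkx2.2-/- replicate 12 or Nkx2.2-/- replicate 29 the count was 7 in each case, and Mag was then at a limma adjusted p of 0.0520, 0.0517 and 0.0530. Slc6a4 lost its call in those 3 runs (limma adjusted p = 0.0741, 0.0870 and 0.0954) and without wild-type replicate 18 (0.0558) or Nkx2.2-/- replicate 22 (0.0673). Ugt8a lost it without any 1 array except Nkx2.2-/- replicate 43 (limma adjusted p from 0.0575 to 0.210), and Gchfr without any 1 of the 10 (0.0591 to 0.167).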

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

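The tests of catecholamine genes, of the cell cycle list and of the list count with an estimated correlation were chosen after the results were seen, as was the setting without the 2 arrays of low 5 prime Gapdh signal. A sample was singled out where it lay far from the other 4 of its group for its range; 21 of 208 groups did so, and chance gives about 1 in 20.

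The 3 prime minus 5 prime Gapdh difference was 2.13 in wild-type replicate 14 and 3.78 in Nkx2.2-/- replicate 43. Wild-type replicate 14 was also apart for Nkx2-2 (6.88, the others from 6.42 to 6.51), the newly formed oligodendrocyte list (7.05) and the catecholaminergic list (5.94). Nkx2.2-/- replicate 43 was low for Slc18a2 (5.10) and Cspg4 (5.47). Wild-type replicate 18 was low for Mbp (10.4, the others from 10.8 to 10.9). Wild-type replicate 21 was low for Lum (5.04). Nkx2.2-/- replicate 11 was high for Mag (5.67) and low for Csf1r (7.82) and Insig1 (6.87). It was also high for the lists of ventral patterning (6.07), radial glia (7.34), cerebellum (6.74) and forebrain and midbrain genes (5.34). Among probe sets without a single gene symbol, which the tests over genes do not use, 3 passed the threshold over all probe sets, all of them lower in the Nkx2.2-/- mice.

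For the lower myelin and serotonergic genes, the real split of the 10 arrays called 11 genes and the highest of the others 3. Only the real split, 1 of 100, gave as many, so chance is argued against for the count of genes. RNA degradation on single arrays is argued against, since all 11 genes kept over 50% of their log2 change without the 2 arrays of low 5 prime Gapdh signal, although Cldn11, Slc6a4 and Gchfr no longer passed there with 4 mice per group. A dissection reaching further caudal in the Nkx2.2-/- mice is argued against as the whole cause: with the mean of the caudal Hox genes as a covariate the myelin and serotonergic lists changed by -0.38 and -0.36, and the lower share of the change kept was 94.6%. Loss of pontine tissue with its other monoaminergic neurons cannot be told apart for the serotonergic genes: the 10 catecholamine genes outside their list had a mean change of -0.049 (95% interval -0.19 to 0.09), but 6 of them are in the dimmer part of all genes, several mark midbrain neurons, and the noradrenaline transporter Slc6a2 was at -0.36 (SE 0.241) against -0.04 (SE 0.0869) for Dbh, which makes noradrenaline. That Slc6a2 value is of its brightest probe set and ran from -0.50 to -0.19 without single arrays. The other, dimmer Slc6a2 probe sets were at 0.001, -0.004 and -0.04. Loss of Nkx2.2 acting on the cells that express the lower genes remains open, as does litter, which was not used here, while with a covariate for sex 9 genes passed.

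For the lower cell cycle genes, the list score was 6.36 in wild-type replicate 18 and 5.93 in Nkx2.2-/- replicate 11, each high in its group, as were Ccnb2 (6.05) and Cdk1 (6.81) in the former and Top2a (6.39) in the latter. Without Nkx2.2-/- replicate 11 the mean change grew to -0.43. Without wild-type replicate 18 it was -0.25 (95% interval -0.47 to -0.03), and with the cerebellum list as a covariate it was -0.26 (-0.41 to -0.11), both with intervals too wide to exclude that 1 array or more cerebellar tissue in wild-type sections may account for over 50% of the change of -0.35. The lower bound of the precursor list's change was -0.0665, which argues against a fall of precursor genes over 50% as large as that of the cell cycle list. Fewer cycling precursors could leave the precursor list's mean unchanged, and they were not tested.

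For the count of lists by the preset correlation chance could not be excluded: the real split gave 12, 28 of 100 splits gave as many, and the highest of the others gave 21. Other splits calling more lists points to a structure among the arrays that genes of a list share. With an estimated correlation the real split gave 2 lists and the highest of the others 0. Only the real split, 1 of 100, gave as many, so chance is argued against for that count.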

How the results depend on the processing

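The log2 change of Nkx2-2 ran from -2.10 to -1.94 and passed wherever it was tested. Mbp and Cnp passed under every alternative run, and Tph2, Mobp and Plxnb3 under every one that tested them, with highest limma adjusted p of 0.00687, 0.0244, 0.0193, 0.0287 and 0.0244. Nkx2-2, Tph2, Mobp, Plxnb3 and Gchfr were not tested where the dimmer genes were left out. Calls were lost under 15 of 22 alternatives for Gchfr, 14 of 23 for Ugt8a, 7 of 23 for Slc6a4, 3 of 23 for Mag and 1 of 23 for Cldn11. Sizes moved too, with log2 changes from -2.94 to -1.68 for Mbp and from -1.19 to -0.56 for Ugt8a. The count of 11 genes was 7 with the dimmer genes left out, 6 of them shared, and 23 probe sets with every probe set tested. With the Gapdh difference as a covariate, chosen after seeing the data, it was 17, with all 11 shared. It ran from 7 to 11 on leaving out single arrays, with 7 without wild-type replicate 15, Nkx2.2-/- replicate 12 or Nkx2.2-/- replicate 29. No gene rose under any of these. The 12 lists became 2 with an estimated correlation and 3 with fry, or 2 with Nkx2-2 left out of its list, and ran from 9 to 19 without single arrays, with 19 without Nkx2.2-/- replicate 11. Without that array 2 passed with an estimated correlation. The 0 lists by score became 6 without that array, and 0 again with Nkx2-2 left out of its list, where camera passed 16. Those 6 were at the smallest possible exact p, whose adjusted value depends on how many lists share it. Leaving out Nkx2-2 did not change the scores of the other lists, so these counts show no gain or loss of their changes. The myelin and serotonergic lists passed in all 28 alternatives each, with mean changes from -0.51 to -0.26 and from -0.40 to -0.34. The estimated correlation together with the 8 arrays of high 5 prime Gapdh signal, chosen after seeing the data, kept the serotonergic list (adjusted p = 0.0231) and not the myelin list (0.0824). The newly formed oligodendrocyte list changed by -0.14 and no longer passed with an estimated correlation (adjusted p = 0.0840) or fry (0.102), which allow for correlation between its genes. In 5 added runs with an estimated correlation it passed under the Gapdh covariate (0.0295), where the myelin and serotonergic lists also passed (0.0295 each), and without wild-type replicate 18 (0.0338), and not in the other 3 (0.0595, 0.0824 and 0.122). The Schwann cell list ran from -0.0335 to 0.0529 without single arrays and passed at 0.0529 without wild-type replicate 15 (adjusted p = 0.0124), and the glucocorticoid list ran from -0.0688 to 0.0718 and passed at 0.0718 without wild-type replicate 21 (0.00388); neither passed with all arrays, and the cause was not tested. A further 92 values not past the threshold changed sign, none larger in size than 0.28. No paired analysis was run, because the litter of each mouse was not used here and the replicate numbers do not give a pairing. Signal over background limits dim genes such as Mog, whose Nkx2.2-/- mean lay above 2.7% of probe sets.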

Other observations

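The Snx5 test and the naming of the genes in this part were chosen after the results were seen; the test of genes beside Nkx2-2 was set before.

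The calls moved both ways when array quality was taken into account. With the Gapdh difference as a covariate, 6 further genes fell: Bcas1 (log2 change -0.82, limma adjusted p = 0.00943), Sirt2 (-0.52, 0.00943) and 9630013A20Rik (-0.33, 0.0474) of the oligodendrocyte lists, Ddc (-1.24, 0.00741) and Slc18a2 (-0.42, 0.01004) of the serotonergic list, and Gltp (-0.41, 0.0469), which encodes a glycolipid transfer protein. Without the 2 arrays of low 5 prime Gapdh signal 10 genes fell, 8 of them shared with the 11, and Ddc and Slc18a2 were the others (limma adjusted p = 0.0464 and 0.0436). Slc6a4, Cldn11 and Gchfr were lost there, at log2 changes of -1.30, -1.11 and -0.42 (limma adjusted p = 0.0520, 0.0520 and 0.192). Over all alternatives the limma adjusted p of Pdgfra stayed at 0.225 or above, at log2 changes from 0.23 to 0.62.

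Hoxc8, a Hox gene of the spinal cord, differed between single Nkx2.2-/- mice. It lay at 7.22, 6.96 and 6.17 in replicates 22, 29 and 43 and at 4.72 and 4.82 in replicates 11 and 12, while the wild-type mice ranged from 4.53 to 4.84.

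Another probe set brought in 2 genes that the brightest one did not call. For 9630013A20Rik 2 of 3 probe sets fell, with log2 changes of -0.86 and -0.68 (limma adjusted p over all probe sets = 0.00144 and 0.0101), while the brightest was at -0.34. For Snx5, a sorting nexin gene that is among the 100 measured genes nearest to Nkx2-2, 1 of 5 probe sets fell, from 6.72 ± 0.083 to 6.10 ± 0.074 (SD, n = 5 each), a log2 change of -0.61 (limma adjusted p over all probe sets = 7.3e-04). Of the others, 2 were at -0.20 (95% interval -0.32 to -0.07) and -0.16 (-0.30 to -0.03), 1 at 0.004 (-0.24 to 0.25) and 1 at 0.22 (-0.08 to 0.52). The last 2 argue against an equal fall of all Snx5 transcripts only if their probes respond alike, which was not tested, and a smaller fall stays open. Chromosome kept from the strain of the targeted cells may alter single probe sets near the gene. Of the 100 neighbours 5 had an unadjusted p under 0.05, or 5% (exact 95% interval 1.64 to 11.3), against 3.23% of all genes, so an excess of changed neighbours cannot be told apart from none, and sequence differences under the probes were not analysed here.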
